A study of Mus musculus with 12 samples.

How the data were processed

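RNA was measured in 12 libraries of mouse gonads at E13.5, 3 each of male PGC, male soma, female PGC and female soma. Per the labels' protocols, Oct4-GFP-positive and GFP-negative cells were separated by flow cytometry, spike-in RNA (ERCC) was added in proportion to cell number, and libraries were made with a directional messenger RNA kit. Groups and replicate numbers were taken from the sample titles, and no sample was left out of the comparisons.

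Per the submitters' processing notes, Trim Galore 0.4.0, TopHat2 2.0.9, HTSeq 0.6.1p1, R 3.3.0, DESeq2 1.12.3, edgeR 3.14.0 and limma 3.28.14 were used with build mm10, without a stated role or order. The strand setting of the counting, the annotation and the gene filter are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart with certainty.

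The authors deposited 2 tables of log2 expression values over the same 12845 genes, the first normalized to cell number and the second to read depth. The abbreviation that names the first table was read as cell number normalization, because spike-in RNA was added per cell and because its library medians ran from 3.59 to 6.07, against 8.56 to 8.82 in the read depth table. No spike-in genes are among those analysed here, so the scaling itself was not checked against spike-in reads.

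The values of the cell number table were inverted to reads: in each library 100% of the deposited log2 values equalled log2 of a whole number plus 0.5, divided by a library-specific effective size, within a tolerance of 0.001 reads. These reads gave the depth of 6454322 to 24791414 per library and the CPM, which are shares of the reads in the table. The log2 values of the deposited read depth table are not a simple log of the reads, and the transform is not given in the sources used here. Every gene had at least 5.07 CPM in at least 3 libraries, so genes at lower levels were not analysed here. SDs and SEs measure the spread between libraries. Floors cover counting error only, and a count of 0 was bounded by 3 reads over the group.

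Genes were located by symbol in GENCODE vM21 (GRCm38): 12409 matched by current symbol and 386 by an older one, and 12774 had one location. Replicates of a group were compared before averaging, and each pair differed beyond sampling noise (chi-square per degree of freedom 5.45 to 31.0). The labels give no sequencing batch.

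The global shift was the difference between groups in the median log2 value of a library over all genes of the cell number table, tested with two-sided exact permutation tests. Genes were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values of all 12 libraries, with 4 group means, an intensity trend and Benjamini-Hochberg adjustment over 12845 genes, at an adjusted p of 0.05. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with adjustment over lists within a comparison. The mitochondrially encoded list had 0 measured members and was not tested. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

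Groups, tests, gene lists, the rule for naming genes and most alternative settings were chosen before the data were examined. Named genes are the 8 with the largest rise and the 8 with the largest fall in each main comparison among genes past the threshold whose groups did not overlap, up to 4 members of each list described (the 2 highest in mean level and the 2 with the largest absolute change), a fixed set of label checks, and the 6 genes with the largest difference between sexes. The rule left out unnamed gene models, small RNAs and pseudogenes. The whole reads were also tested with limma's voom, an alternative added after the data were seen, because the deposited unit was log2.

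The alternatives were leaving out each library, leaving out the lowest 25% of genes by level, a log2 fold change of at least 1, median centring, quantile normalization, the other deposited table, other variance settings, array weights, a replicate block, an estimated correlation and fry for lists. Leaving out 3 female libraries, voom and reads per effective size were added later. The pipeline was tested on simulated data for 12845 genes with 200 changed. For PGCs against soma as the mean of both sexes, the read depth values recovered 89.6%, 98.5% and 100% of genes simulated at a log2 change of 0.5, 1 and 2, and the cell number values recovered 5.97%, 61.2% and 92.4%. A simulated moved list was called in each comparison and 0 of 28 other lists were. The changes were added on the scale of each table's own values. The read depth values move by only 0.29 (genes under 100 mean reads) to 0.77 (at least 10000) for each log2 unit of reads. The percentages therefore do not compare the sensitivity of the read depth and cell number values at an equal change in reads. The simulated noise was drawn independently for each gene and library. The simulation therefore cannot show how often correlated genes or a library-wide scaling error would give false calls.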

Results

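RNA sequencing libraries from mouse fetal gonads at E13.5 were compared between primordial germ cells (PGCs, the precursors of eggs and sperm) and the gonadal soma. Embryos carried an Oct4 green fluorescent protein (GFP) reporter, which is active in germ cells, and gonads were sorted by flow cytometry into GFP-positive PGCs and GFP-negative soma. The 12 libraries fall into 4 groups of 3: male PGC, male soma, female PGC and female soma. External control RNA was added in proportion to the number of sorted cells, so that transcript levels can be expressed per cell as well as per read. The series asks about hypertranscription, a global rise in transcript output per cell. Each deposited table held 12845 genes, and the reads recovered from the cell number table numbered between 6454322 (female PGC replicate 2) and 24791414 (male soma replicate 2) per library. The median gene had between 202 and 894 reads in a library.

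The sorted populations carried the transcripts of the cells they were named for. Pou5f1, which encodes Oct4 (chromosome 17, 35506018 to 35510772 of GRCm38, gene ENSMUSG00000024406.16), stood at 759 ± 21.6 CPM in male PGCs against 1.08 ± 0.485 in male soma, and at 273 ± 52.7 in female PGCs against 5.39 ± 3.61 in female soma (SD, n = 3 in each group, where CPM are reads scaled to the library total). The germ cell RNA helicase Ddx4 and the germ cell RNA-binding protein Dazl were higher in PGCs by log2 fold changes of 5.44 ± 0.33 and 5.89 ± 0.35 (SE). Wt1, a transcription factor of the gonadal soma, had a log2 fold change of -4.29 ± 0.25. Ddx3y, a helicase gene on the Y chromosome, had 0 reads in all 3 female PGC libraries and 30.6 ± 2.92 CPM in male PGCs, at least 401-fold higher when 3 reads over the female group are taken as the limit. Xist, the RNA that coats the inactive X chromosome, reached 2040 ± 121 CPM in female soma and 2.12 ± 0.759 in male soma.

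PGCs held more transcripts per cell than the surrounding soma across most of the measured transcriptome. In the cell number normalized table, the median log2 value over all 12845 genes was 5.83 ± 0.0433 in male PGCs, 4.62 ± 0.545 in male soma, 5.94 ± 0.126 in female PGCs and 3.74 ± 0.191 in female soma (SD, n = 3). The median of PGCs was therefore 1.70 ± 0.171 log2 units (SE) above that of soma, a 3.26-fold difference, and every PGC library lay above every soma library of its sex. A two-sided exact permutation test of the library medians within sex gave p = 0.005, the smallest value that its 400 arrangements allow. The shift was 1.21 ± 0.316 in males (2.31-fold) and 2.20 ± 0.132 in females (4.59-fold). With 3 libraries against 3 the exact two-sided p was 0.1 in each sex, the smallest this design can give. The female shift exceeded the male shift by 0.99 ± 0.342 log2 units, with an exact permutation p of 0.01. Male soma replicate 3 stood apart from the other male soma libraries, at a median of 5.25 against 4.33 and 4.29, and without it the difference between the sexes was 0.676 ± 0.14. The exact p of that difference was 0.055 over the genes above the median mean level. It was 0.095 for the total reads per effective library size, a measure chosen after the data were seen. Without female soma replicates 1 and 2 and female PGC replicate 2, also a later choice that left 1 female soma library, the difference was 0.83 with an exact p of 0.275.

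**Figure D1:**
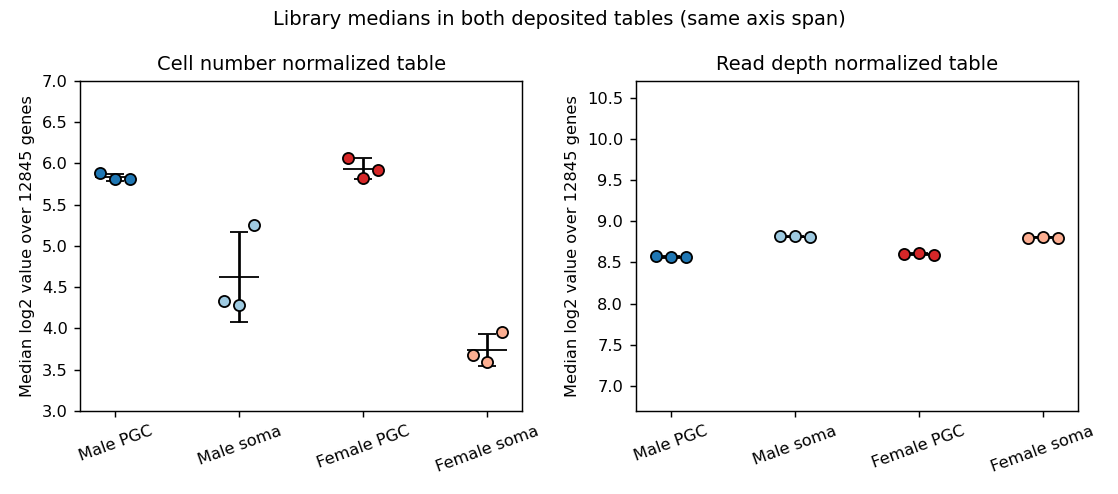
Median log2 value over 12845 genes for each of the 12 libraries (points), with the group mean and SD (n = 3), in the cell number normalized table (left) and the read depth normalized table (right). Both vertical axes span 4 log2 units. Per cell, male and female PGC libraries lie at 5.81 to 6.07 and soma libraries at 3.59 to 5.25, while by read depth all 12 medians lie between 8.56 and 8.82.

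At the level of single genes, 9541 of 12845 genes were higher and 2115 lower per cell in PGCs as the mean of both sexes (limma, adjusted p under 0.05), with a median log2 fold change of 1.89 over all genes. In males 8215 genes were higher and 2541 lower, and in females 9922 were higher and 1481 lower. The genes higher in both sexes numbered 7935, against 6346 for independent lists of those sizes, and those lower in both numbered 1278, against 293. In the read depth normalized table, whose library medians lay 0.22 log2 units lower in PGCs, 5321 genes were higher and 5817 lower, and median centring of that table gave 6446 higher and 4855 lower. Of the genes lower by read depth, 2527 were higher per cell, 2115 were also lower per cell and 1175 did not pass the threshold per cell. Median centring turned the per-cell split into 6200 genes higher and 5054 lower. By read depth, male PGCs had 5026 genes higher and 5607 lower than male soma, and female PGCs 4968 higher and 5439 lower than female soma.

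**Figure D2:**
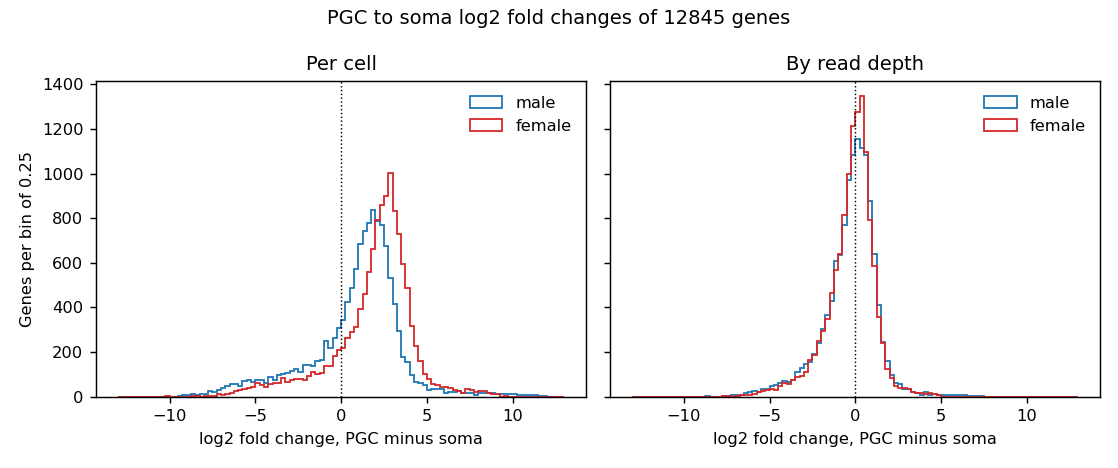
Distribution of the log2 fold change between PGCs and soma over 12845 genes in males (blue) and females (red), per cell (left) and by read depth (right), with the number of genes per bin of 0.25 on the vertical axis. The per-cell median over genes is 1.42 in males and 2.36 in females, and the read depth medians are -0.06 and -0.05.

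Gene by gene values below are from the read depth normalized table unless said to be per cell, with log2 fold changes given as estimate ± SE. That table draws low values together: over genes with a mean under 100 reads its values moved by 0.287 for each log2 unit of reads, and over genes with at least 10000 mean reads by 0.769. Its fold changes therefore often understate those of the reads, but not always, and levels are quoted as CPM. For PGCs against soma, the median of translation factors was 0.44 by read depth and 0.35 with voom on the reads. For cytosolic ribosomal protein genes these medians were 0.58 and 0.51, while for ribosome biogenesis genes they were 0.87 and 0.94. Over all genes the median was -0.04 by read depth and -0.29 with voom.

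Genes of germ cells and pluripotency had the largest rises in PGCs. All 24 measured members of the germ cell and pluripotency list were higher (24 higher and 0 lower adjusted over the list alone). Germ cell and pluripotency genes had a median log2 fold change of 4.53 (camera adjusted p = 2.44e-08, and adjusted p = 0.258 with an estimated correlation). Pou5f1 rose by 5.96 ± 0.22 (adjusted p = 5.17e-12), and per cell by 9.77. Dppa3, which protects imprints in the early embryo, rose by 5.89 ± 0.24, and Dppa4 and Dppa5a, both markers of pluripotent cells, by 5.79 ± 0.27 and 5.77 ± 0.24. The zinc finger factor Sall4 rose by 5.77 ± 0.27, and Tex19.1, which restrains retrotransposons in germ cells, by 5.79 ± 0.27. Kit, the receptor for stem cell factor, rose by 1.40 ± 0.10 from a soma level of 71.1 CPM in males.

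Small RNA and meiosis genes followed. All 18 measured genes of the piRNA pathway, which silences transposons in the germ line, were higher in PGCs (18 higher and 0 lower adjusted over the list alone). The piRNA pathway had a median log2 fold change of 3.23 (camera adjusted p = 1.19e-06, and adjusted p = 0.281 with an estimated correlation). The RNA helicase Mov10l1 rose by 5.83 ± 0.37, Mael by 5.57 ± 0.40 and Tex15 by 3.09 ± 0.26. All 30 meiotic prophase genes were higher as the mean of both sexes (30 higher and 0 lower adjusted over the list alone). Meiotic prophase genes had a median log2 fold change of 2.79 (camera adjusted p = 1.63e-07, and adjusted p = 0.281 with an estimated correlation). The meiotic cohesin gene Smc1b rose by 5.51 ± 0.42, the synaptonemal complex gene Sycp1 by 5.30 ± 0.41 and the cohesin gene Stag3 by 3.77 ± 0.22. Of 9 genes of the male germ cell programme, 7 were higher and 1 lower as the mean of both sexes (7 higher and 1 lower adjusted over the list alone). In males 8 were higher and 0 lower, at a median of 3.16 (camera adjusted p = 0.0019, and 0.11 with an estimated correlation). In females 3 were higher and 2 lower, at a median of 0.10, without a call (camera adjusted p = 0.706, and 0.744 with an estimated correlation). Male germ cell programme genes had a median log2 fold change of 1.65 (camera adjusted p = 0.0289, and adjusted p = 0.258 with an estimated correlation). Nanos2, an RNA-binding protein of the male germ line, rose by 3.79 ± 0.24 as the mean of both sexes, with 0.627, 0.31 and 0.478 CPM in female PGCs. The cell cycle inhibitor Cdkn1b stood at -1.42 ± 0.08 by read depth and 0.06 per cell. The call of the male germ cell programme ended in the cell number table (median 4.77, camera adjusted p = 0.382) and with voom on the recovered reads, an alternative chosen after the data were seen (median 2.60, camera adjusted p = 0.121), although both medians were larger.

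Genes for making ribosomes, proteins and messenger RNA were higher in PGCs even at equal read depth, so that their per-cell rise lay above that of the median gene. Of 34 ribosome biogenesis genes, 31 were higher and 2 lower (31 higher and 2 lower adjusted over the list alone), with a per-cell median of 3.11. Ribosome biogenesis genes had a median log2 fold change of 0.87 (camera adjusted p = 5.41e-07, and adjusted p = 0.281 with an estimated correlation). Nucleolin (Ncl) rose by 1.07 ± 0.05, nucleophosmin (Npm1) by 0.97 ± 0.05, Polr1b, a core subunit of RNA polymerase I, by 1.44 ± 0.06 and the small nucleolar RNA-binding protein gene Nhp2 by 1.52 ± 0.09. Of 76 cytosolic ribosomal protein genes, 69 were higher and 1 lower (69 higher and 1 lower adjusted over the list alone). Cytosolic ribosomal protein genes had a median log2 fold change of 0.58 (camera adjusted p = 3.82e-11, and adjusted p = 0.281 with an estimated correlation). Rpl4 rose by 0.70 ± 0.05 and Rpsa by 0.65 ± 0.05, and the germ line paralogs Rpl39l and Rpl10l by 4.22 ± 0.14 and 3.91 ± 0.25, where shared reads between near-identical copies leave the values uncertain. Translation factors gave 26 higher and 4 lower of 32 (26 higher and 4 lower adjusted over the list alone). Translation factors had a median log2 fold change of 0.44 (camera adjusted p = 0.000152, and adjusted p = 0.281 with an estimated correlation). The elongation factors Eef1a1 and Eef2 rose by 0.23 ± 0.05 and 0.43 ± 0.05.

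Of 39 RNA polymerase II transcription and elongation genes, 31 were higher and 4 lower (32 higher and 4 lower adjusted over the list alone), with a per-cell median of 2.81. RNA polymerase II genes had a median log2 fold change of 0.59 (camera adjusted p = 3.35e-05, and adjusted p = 0.148 with an estimated correlation). Polr2a, the largest subunit of the polymerase, rose by 0.97 ± 0.05, Supt16, part of the histone chaperone FACT, by 1.38 ± 0.04 and the initiation factor gene Gtf2e2 by 1.65 ± 0.06. Chromatin remodelling and acetylation genes gave 20 higher and 2 lower of 27 (20 higher and 2 lower adjusted over the list alone). Chromatin remodelling and acetylation genes had a median log2 fold change of 0.38 (camera adjusted p = 0.00168, and adjusted p = 0.281 with an estimated correlation). The remodellers Smarca5 and Chd4 rose by 1.33 ± 0.06 and 0.40 ± 0.04, and the acetyltransferase Kat7 by 1.22 ± 0.06. Oxidative phosphorylation genes gave 64 higher and 4 lower of 76 (64 higher and 4 lower adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.51 (camera adjusted p = 9.14e-08, and adjusted p = 0.281 with an estimated correlation). The ATP synthase gene Atp5b rose by 1.03 ± 0.04 and Cox5a by 1.53 ± 0.07, and Atp5a1 stood at -0.07 ± 0.05 (adjusted p = 0.215).

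DNA repair genes were higher in PGCs in 24 of 25 cases and lower in 1 (24 higher and 1 lower adjusted over the list alone). DNA repair genes had a median log2 fold change of 1.50 (camera adjusted p = 9.14e-08, and adjusted p = 0.148 with an estimated correlation). The checkpoint kinase gene Atr rose by 2.30 ± 0.09, the Fanconi anaemia gene Fancd2 by 2.10 ± 0.06 and the mismatch repair gene Msh6 by 1.54 ± 0.06. Cell cycle genes gave 21 higher and 2 lower of 28 (21 higher and 2 lower adjusted over the list alone). Cell cycle genes had a median log2 fold change of 0.66 (camera adjusted p = 0.000244, and adjusted p = 0.405 with an estimated correlation). The spindle checkpoint kinase gene Bub1 rose by 2.07 ± 0.07 and the centromere gene Cenpf by 1.81 ± 0.06, while the proliferation marker Mki67 stood at -0.34 ± 0.10 by read depth and 1.55 per cell. By read depth the DNA methylation list went both ways, with 2 of 7 genes higher and 4 lower (2 higher and 4 lower adjusted over the list alone), and no call for the list (camera adjusted p = 0.663, and adjusted p = 0.736 with an estimated correlation). Per cell the methylation list gave 5 higher and 1 lower, with a median of 1.20. The maintenance methyltransferase Dnmt1 and the oxidase Tet1 rose by 1.02 ± 0.05 and 1.58 ± 0.09, and Tet3 changed by -2.53 ± 0.11. The de novo methyltransferase Dnmt3a stood at -1.35 ± 0.09 by read depth and 0.27 per cell. By read depth the Myc network split as well, with 5 of 11 genes higher and 6 lower (5 higher and 6 lower adjusted over the list alone). Myc network genes had a median log2 fold change of -0.23 (camera adjusted p = 0.932, and adjusted p = 0.958 with an estimated correlation). The list's median was below 0 while camera's direction was up, and per cell it gave 8 higher and 1 lower, with a median of 1.62. Mycn and Mga rose by 1.04 ± 0.10 and 1.11 ± 0.06, and Myc changed by -3.35 ± 0.13 with 1.38 CPM in male PGCs.

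The soma held the blood, matrix and steroid cell transcripts. All 8 measured erythroid genes were lower in PGCs (0 higher and 8 lower adjusted over the list alone), led by the embryonic globins Hbb-y (-8.56 ± 0.22) and Hba-x (-8.33 ± 0.22), the red cell anion exchanger Slc4a1 (-7.79 ± 0.18) and the haem synthesis enzyme Alas2 (-7.24 ± 0.26). Erythroid cell genes had a median log2 fold change of -6.66 (camera adjusted p = 0.000342, and adjusted p = 0.258 with an estimated correlation). All 21 extracellular matrix genes were lower (0 higher and 21 lower adjusted over the list alone), with Col3a1 at -7.23 ± 0.25, Col1a2 at -7.15 ± 0.23, Col1a1 at -7.10 ± 0.23 and elastin (Eln) at -7.04 ± 0.16. Extracellular matrix genes had a median log2 fold change of -4.54 (camera adjusted p = 9.14e-08, and adjusted p = 0.258 with an estimated correlation). Per cell 16 of them were lower and 3 higher, among the latter fibronectin (Fn1), at -0.45 ± 0.07 by read depth and 1.40 per cell. Gonadal stroma and progenitor genes gave 1 higher and 11 lower of 12 (1 higher and 11 lower adjusted over the list alone). Gonadal stroma and progenitor genes had a median log2 fold change of -4.82 (camera adjusted p = 0.000838, and adjusted p = 0.281 with an estimated correlation). Pdgfra, a receptor of mesenchymal cells, changed by -6.29 ± 0.23 and the transcription factor Tcf21 by -6.01 ± 0.20. All 14 macrophage genes were lower (0 higher and 14 lower adjusted over the list alone), with the growth factor receptor Csf1r at -5.16 ± 0.24. Macrophage genes had a median log2 fold change of -3.72 (camera adjusted p = 1.94e-05, and adjusted p = 0.281 with an estimated correlation). Of 12 endothelial genes 9 were lower and 1 higher (1 higher and 9 lower adjusted over the list alone), with Kdr at -4.33 ± 0.17 and Pecam1, the member that rose, at 2.12 ± 0.17. Endothelial cell genes had a median log2 fold change of -1.42 (camera adjusted p = 0.0183, and adjusted p = 0.358 with an estimated correlation).

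All 12 Leydig cell genes were lower (0 higher and 12 lower adjusted over the list alone), with the steroid enzyme genes Hsd3b1 and Hsd3b6, which share sequence and may share reads, at -5.81 ± 0.21 and -5.27 ± 0.18. Leydig cell genes had a median log2 fold change of -3.64 (camera adjusted p = 9.09e-05, and adjusted p = 0.104 with an estimated correlation). Of 14 Sertoli cell genes 13 were lower and 1 higher (1 higher and 13 lower adjusted over the list alone). Sertoli cell genes had a median log2 fold change of -1.58 (camera adjusted p = 0.00543, and adjusted p = 0.281 with an estimated correlation). Sox9, which directs Sertoli cell fate, changed by -3.05 ± 0.16, and Etv5, the gene that rose, by 1.17 ± 0.08. Pregranulosa genes gave 2 higher and 10 lower of 14 (2 higher and 11 lower adjusted over the list alone), with Wnt4 at -4.35 ± 0.13 and Runx1 at -3.74 ± 0.24. Pregranulosa cell genes had a median log2 fold change of -1.46 (camera adjusted p = 0.0458, and adjusted p = 0.281 with an estimated correlation). Imprinted genes were lower in 19 of 21 cases and higher in 1 (1 higher and 19 lower adjusted over the list alone), with Dlk1 at -5.14 ± 0.08, Meg3 at -5.16 ± 0.16 and H19 at -4.26 ± 0.11. Imprinted genes had a median log2 fold change of -2.86 (camera adjusted p = 3.17e-06, and adjusted p = 0.148 with an estimated correlation). Immediate early and heat shock genes gave 4 higher and 14 lower of 19 (4 higher and 14 lower adjusted over the list alone). Immediate early and heat shock genes had a median log2 fold change of -1.19 (camera adjusted p = 0.0458, and adjusted p = 0.405 with an estimated correlation). Jun and Egr1 changed by -3.53 ± 0.14 and -3.08 ± 0.18, and the chaperone genes Hsp90aa1 and Hspa8 rose by 2.38 ± 0.07 and 0.95 ± 0.05. Per cell 8 immediate early and heat shock genes were higher and 8 lower, with a median of -0.017. The per-cell counts were 3 higher and 9 lower for Leydig, 3 higher and 9 lower for Sertoli, 5 higher and 7 lower for pregranulosa and 4 higher and 13 lower for imprinted genes.

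Glycolysis genes gave 3 higher and 12 lower of 16 (3 higher and 12 lower adjusted over the list alone), without a call for the list (camera adjusted p = 0.0745, and adjusted p = 0.533 with an estimated correlation), and the list median turned from -0.56 by read depth to 1.18 per cell. Lactate dehydrogenase (Ldha) changed by -2.69 ± 0.11 and Tpi1 by -2.11 ± 0.08, while Pkm rose by 0.46 ± 0.05. The mesonephric epithelium, Y-linked and X-linked escape lists had no call (camera adjusted p = 0.664, 0.926 and 0.96). The common reference genes depended on the scale: Gapdh was -0.39 and Actb -1.05 by read depth, but 1.48 and 0.66 per cell. The immediate early and heat shock call ended without male PGC replicate 3, male soma replicate 1 or female soma replicate 2 (medians -1.16, -1.17 and -1.14, camera adjusted p = 0.0513, 0.0502 and 0.0593), and the pregranulosa call without female soma replicate 1 (median -1.43, camera adjusted p = 0.0527). The immediate early and heat shock call also ended in the cell number table (camera adjusted p = 0.0514), without the 3 female libraries named above (median -1.22, camera adjusted p = 0.069) and with voom (median -2.25, camera adjusted p = 0.138). Voom ended the Sertoli, pregranulosa, endothelial and erythroid calls too (camera adjusted p = 0.0759, 0.121, 0.0759 and 0.0587), although their medians were larger in size, at -3.29, -2.39, -4.34 and -10.51. The lower and upper quartiles over all genes also lay further apart, at -1.73 and 0.60 with voom against -0.93 and 0.58. In all, 22 of 28 lists were called, 12 higher and 10 lower, and none was called with an estimated correlation, where the smallest adjusted p was 0.104. The labels do not say whether replicates came from separate litters or pools, so the tests measure only the spread between these samples.

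**Figure D3:**
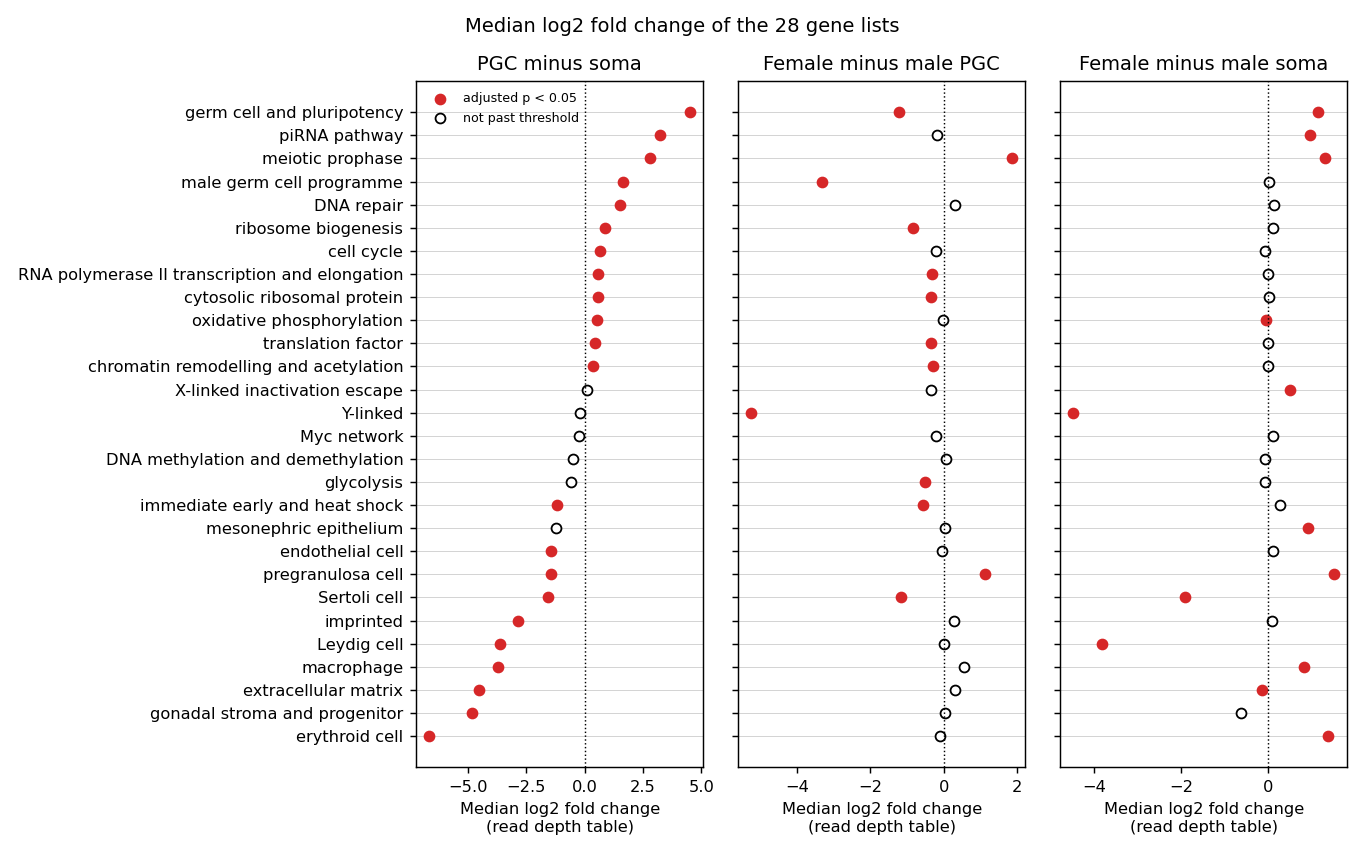
Median log2 fold change of each of the 28 gene lists in the read depth normalized table for PGCs against soma (left), female against male PGCs (middle) and female against male soma (right). Filled red points passed camera's adjusted p of 0.05 with the preset correlation and open points did not, and the medians run from -6.66 (erythroid cell) to 4.53 (germ cell and pluripotency) in the left panel.

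Female and male PGCs differed in meiotic genes, in the male germ cell programme and in ribosome and translation genes. By read depth 4212 genes were higher and 4169 lower in female PGCs, and per cell 3125 were higher and 2279 lower, with a per-cell median over all genes of 0.08. The largest rise was that of Stra8 (chromosome 6, 34920163 to 34939344 of GRCm38), the gatekeeper of meiotic entry, at 6.22 ± 0.83 (adjusted p = 1.72e-05), from 3.17 ± 1.93 to 564 ± 99.9 CPM (SD, n = 3). Meiotic prophase genes were higher in 27 of 30 cases and lower in none (28 higher and 0 lower adjusted over the list alone). Meiotic prophase genes had a median log2 fold change of 1.88 (camera adjusted p = 1.02e-06, and adjusted p = 0.666 with an estimated correlation). Mei1, needed for meiotic double-strand breaks, rose by 6.16 ± 0.58, and Stag3 and Syce2 by 1.14 ± 0.31 and 1.11 ± 0.16. Transcription factor genes were also among the 8 largest rises: Cdx2 (4.88 ± 0.39), Gata2 (4.54 ± 0.16), Dlx3 (4.49 ± 0.29) and Msx1 (4.46 ± 0.24). Beside Stra8 and Mei1, the others were the class I histocompatibility gene H2-K1 (4.47 ± 0.26) and the imprinted gene Phlda2 (4.34 ± 0.21).

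Male PGCs were higher in 8 of 9 genes of the male germ cell programme (0 higher and 8 lower adjusted over the list alone, as female minus male). Male germ cell programme genes had a median log2 fold change of -3.32 (camera adjusted p = 3.88e-05, and adjusted p = 0.0984 with an estimated correlation). Nanos2 (chromosome 7, 18987400 to 18988962) changed by -6.01 ± 0.34, from 64.9 ± 23.0 CPM in males to 0.471 ± 0.158 in females. The Nodal antagonists Lefty1 and Lefty2 changed by -5.54 ± 0.23 and -5.87 ± 0.26, the transcription factor Egr4 by -5.23 ± 0.32 and Pmaip1, which promotes apoptosis, by -6.37 ± 0.28. All 5 Y-linked genes were lower in females (0 higher and 5 lower adjusted over the list alone), with the translation factor gene Eif2s3y at -6.99 ± 0.41, the demethylase gene Kdm5d at -5.26 ± 0.26 and Uba1y at -7.04 ± 0.26, whose X-linked relative may share reads with it. Y-linked genes had a median log2 fold change of -5.26 (camera adjusted p = 0.000153, and adjusted p = 0.186 with an estimated correlation). Pluripotency genes were mostly lower in females, 14 of 24 against 3 higher (3 higher and 14 lower adjusted over the list alone). Germ cell and pluripotency genes had a median log2 fold change of -1.22 (camera adjusted p = 0.0224, and adjusted p = 0.754 with an estimated correlation). Pou5f1 changed by -1.40 ± 0.30, while the X-linked homeobox genes Rhox9 and Rhox6 rose by 2.99 ± 0.50 and 2.80 ± 0.52, and Dazl differed by -0.02 ± 0.49 (adjusted p = 0.97).

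Genes for making ribosomes and proteins were mostly lower in female than in male PGCs. Ribosome biogenesis genes were lower in 30 of 34 cases and higher in none (0 higher and 30 lower adjusted over the list alone), and per cell in 23. Ribosome biogenesis genes had a median log2 fold change of -0.82 (camera adjusted p = 3.87e-10, and adjusted p = 0.292 with an estimated correlation). The processing factor genes Rrp9 and Utp15 changed by -1.95 ± 0.12 and -1.65 ± 0.09, and Ncl by -0.64 ± 0.07. Cytosolic ribosomal protein genes gave 5 higher and 60 lower of 76 (5 higher and 60 lower adjusted over the list alone), with Rplp0 at -1.09 ± 0.08. Cytosolic ribosomal protein genes had a median log2 fold change of -0.34 (camera adjusted p = 2.05e-08, and adjusted p = 0.673 with an estimated correlation). Per cell 10 were lower and 1 higher. Translation factors gave 1 higher and 21 lower of 32 (1 higher and 21 lower adjusted over the list alone), with the helicase gene Eif4a1 at -0.99 ± 0.07. Translation factors had a median log2 fold change of -0.34 (camera adjusted p = 0.000529, and adjusted p = 0.666 with an estimated correlation). Per cell 8 translation factors were lower and 0 higher. RNA polymerase II genes gave 5 higher and 23 lower of 39 (5 higher and 24 lower adjusted over the list alone), with Polr2e at -1.46 ± 0.08 and Polr2a at -0.07 ± 0.07 (adjusted p = 0.38). RNA polymerase II genes had a median log2 fold change of -0.31 (camera adjusted p = 0.00204, and adjusted p = 0.292 with an estimated correlation). Per cell 14 RNA polymerase II genes were lower and 3 higher. Chromatin genes gave 4 higher and 17 lower of 27 (4 higher and 17 lower adjusted over the list alone). Chromatin remodelling and acetylation genes had a median log2 fold change of -0.28 (camera adjusted p = 0.0291, and adjusted p = 0.71 with an estimated correlation). Per cell 5 chromatin genes were lower and 1 higher, and the list was no longer called, at a median of -0.29 (camera adjusted p = 0.0854). Glycolysis genes gave 3 higher and 9 lower of 16 (3 higher and 9 lower adjusted over the list alone), with Pgam1 at -1.71 ± 0.11 and the glucose transporter Slc2a1 at -1.61 ± 0.13. Glycolysis genes had a median log2 fold change of -0.52 (camera adjusted p = 0.0378, and adjusted p = 0.713 with an estimated correlation). Immediate early and heat shock genes gave 1 higher and 14 lower of 19 (1 higher and 14 lower adjusted over the list alone). Immediate early and heat shock genes had a median log2 fold change of -0.56 (camera adjusted p = 0.00492, and adjusted p = 0.66 with an estimated correlation).

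Somatic markers also differed between the PGC groups. Sertoli cell genes gave 2 higher and 9 lower in female PGCs of 14 (2 higher and 9 lower adjusted over the list alone). Sertoli cell genes had a median log2 fold change of -1.17 (camera adjusted p = 0.0224, and adjusted p = 0.666 with an estimated correlation). The anti-Müllerian hormone gene Amh changed by -4.70 ± 0.31, from 42.0 ± 22.3 CPM in male PGCs, where male soma held 437 ± 47.8. Over the 14 Sertoli genes the median level in male PGCs was 14.8%, 6.6% and 7.03% of the male soma level in replicates 1, 2 and 3, against 0.227%, 0.402% and 0.357% for Leydig genes. In the same libraries pregranulosa genes stood at 29.1%, 37.5% and 30.8% and endothelial genes at 7.42%, 6.21% and 5.37%. Male soma is not the tissue of pregranulosa cells, and Foxl2 stood at 1.09, 0.766 and 1.74 CPM there. The pregranulosa percents in male PGCs were therefore not read as RNA of those cells. Pregranulosa genes gave 10 higher and 1 lower of 14 (11 higher and 1 lower adjusted over the list alone), with the homeobox gene Irx3 at 3.61 ± 0.20 and the Wnt feedback genes Axin2 and Nkd1 at 1.16 ± 0.12 and 2.31 ± 0.13. Pregranulosa cell genes had a median log2 fold change of 1.125 (camera adjusted p = 0.00276, and adjusted p = 0.292 with an estimated correlation). Their median level in female PGCs was 31.2%, 37.4% and 27.2% of the female soma level in replicates 1, 2 and 3. Foxl2 was low, at 1.25, 4.34 and 0.956 CPM in those libraries against 51.5 to 71.2 in female soma. The rise of the list was therefore not read as pregranulosa cell RNA. In female PGC replicate 2, stroma genes stood at 4.96% of the female soma level, against 0.89% and 0.334% in replicates 1 and 3. Single genes of uncalled lists moved as well. The cyclin gene Ccne2 rose by 2.17 ± 0.21 and Ccnb1 changed by -1.34 ± 0.15, Brca2 rose by 1.23 ± 0.12, and Tet1 changed by -1.67 ± 0.13. The largest absolute change in the piRNA pathway was that of Tdrd5, at -2.37 ± 0.23. The glycolysis call ended without male PGC replicate 1 or 2 or female PGC replicate 1 or 2 (medians -0.47, -0.53, -0.45 and -0.48, camera adjusted p = 0.0561, 0.0985, 0.051 and 0.0514), and the chromatin call without male PGC replicate 3 (median -0.26, camera adjusted p = 0.0667). The Sertoli call ended with voom, with a larger median of -3.16 (camera adjusted p = 0.087). In all, 13 of 28 lists were called and none with an estimated correlation, where the smallest adjusted p was 0.0984.

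Female and male soma differed in steroid and supporting cell genes and in genes of the sex chromosomes. By read depth 1713 genes were higher and 1417 lower in female soma, fewer than between the PGC groups. Per cell 367 were higher and 8171 lower, with a median over all genes of -0.86. The per-cell changes between soma groups contain that shift, which was not subtracted. Xist (chromosome X, 103460366 to 103483254 of GRCm38) rose by 8.10 ± 0.43 (adjusted p = 1.87e-08). The steroid enzymes Cyp17a1 (chromosome 19, 46667165 to 46673172) and Cyp11a1 had the largest falls, with -8.84 ± 0.34 and -7.73 ± 0.35, and Cyp17a1 went from 1753 ± 362 CPM in male soma to 1.11 ± 0.501 in female soma. Without female soma replicates 1 and 2 and female PGC replicate 2, where transcripts of the other sorted population stood out, a choice made after the data were seen, 725 genes were higher and 714 lower. That setting left 1 female soma library, so the spread of its group was taken from the other groups. The setting kept the male PGC libraries, with the Sertoli transcripts given above.

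Genes of Leydig cells, which make androgens, were lower in females in 11 of 12 cases and higher in 1 (1 higher and 11 lower adjusted over the list alone). Leydig cell genes had a median log2 fold change of -3.82 (camera adjusted p = 6.81e-18, and adjusted p = 0.000586 with an estimated correlation). Star, which carries cholesterol into mitochondria, changed by -6.03 ± 0.23, Hsd3b1 by -5.58 ± 0.30 and the lipoprotein receptor Scarb1 by -3.09 ± 0.09. Sertoli cell genes gave 1 higher and 11 lower of 14 (1 higher and 11 lower adjusted over the list alone), with Amh at -6.64 ± 0.31, Cst9 at -4.59 ± 0.28 and Sox9 at -1.45 ± 0.23. Sertoli cell genes had a median log2 fold change of -1.92 (camera adjusted p = 4.49e-12, and adjusted p = 0.029 with an estimated correlation). Pregranulosa genes, of the female supporting lineage, gave 11 higher and 0 lower of 14 (12 higher and 0 lower adjusted over the list alone). Pregranulosa cell genes had a median log2 fold change of 1.52 (camera adjusted p = 3.4e-11, and adjusted p = 0.0206 with an estimated correlation). Foxl2 (chromosome 9, 98955288 to 98958543), a transcription factor of ovarian supporting cells, rose by 3.98 ± 0.31, Irx3 by 4.22 ± 0.20 and the activin antagonist follistatin (Fst) by 3.71 ± 0.27. Among the other large changes, the cerebellin gene Cbln1 changed by -5.91 ± 0.13 and the prokineticin receptor Prokr2 by -5.38 ± 0.32. Crhr1, the receptor for corticotropin releasing hormone, had 0 reads in all female soma libraries and 47.6 ± 6.66 CPM in male soma, at least 371-fold higher with 3 reads over the female group as the limit. The muscarinic receptor Chrm4, the growth cone gene Gap43 and the long noncoding RNA Miat rose by 3.57 ± 0.18, 3.55 ± 0.69 and 3.27 ± 0.56.

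By read depth all 5 genes of the X-linked escape list were higher in female soma (5 higher and 0 lower adjusted over the list alone). They include Xist, the RNA of the inactive X itself, so not all 5 are escape genes. With Xist the list mean was 1.91, and the list was not tested without it. The demethylase gene Kdm6a stood at 0.55 ± 0.10 by read depth and -0.16 per cell, against the per-cell median of -0.86. X-linked escape genes had a median log2 fold change of 0.51 (camera adjusted p = 0.000238, and adjusted p = 0.0255 with an estimated correlation). Per cell 1 gene of this list, which holds Xist, was higher and 2 were lower. All 5 Y-linked genes were lower (0 higher and 5 lower adjusted over the list alone). Y-linked genes had a median log2 fold change of -4.48 (camera adjusted p = 9.03e-08, and adjusted p = 0.0255 with an estimated correlation). Extracellular matrix genes gave 1 higher and 7 lower of 21 (2 higher and 7 lower adjusted over the list alone), with the basement membrane collagens Col4a1 and Col4a2 at -2.38 ± 0.14 and -2.11 ± 0.11. Extracellular matrix genes had a median log2 fold change of -0.15 (camera adjusted p = 0.0109, and adjusted p = 0.639 with an estimated correlation). Per cell 1 matrix gene was higher and 16 lower. The stroma list had no call (camera adjusted p = 0.213, and adjusted p = 0.791 with an estimated correlation), but its member Nr5a1, a regulator of steroidogenesis, changed by -2.56 ± 0.45. Blood cell markers were higher in female soma by read depth. Erythroid genes rose in 6 of 8 cases (6 higher and 0 lower adjusted over the list alone) and made up 2.96%, 2.74% and 1.76% of reads in female soma against 0.343%, 0.86% and 0.418% in male soma. Erythroid cell genes had a median log2 fold change of 1.36 (camera adjusted p = 0.000238, and adjusted p = 0.23 with an estimated correlation). Hbb-y rose by 2.07 ± 0.31. Macrophage genes rose in 11 of 14 cases (14 higher and 0 lower adjusted over the list alone), with Mrc1 at 1.07 ± 0.26. Macrophage genes had a median log2 fold change of 0.81 (camera adjusted p = 1.21e-05, and adjusted p = 0.321 with an estimated correlation). Mesonephric epithelium genes rose in 5 of 6 cases (5 higher and 0 lower adjusted over the list alone), with Ret at 1.95 ± 0.29. Mesonephric epithelium genes had a median log2 fold change of 0.92 (camera adjusted p = 0.000838, and adjusted p = 0.029 with an estimated correlation). Per cell the erythroid list gave 3 higher and 0 lower, the macrophage list 0 higher and 0 lower with a median of 0.22, and the mesonephric list 1 higher and 0 lower. Oxidative phosphorylation genes gave 0 higher and 13 lower of 76 (0 higher and 7 lower adjusted over the list alone), a call that ended without male soma replicate 1 or female soma replicate 1 or 3 (medians -0.03, -0.05 and -0.05, camera adjusted p = 0.122, 0.0592 and 0.0881). Oxidative phosphorylation genes had a median log2 fold change of -0.06 (camera adjusted p = 0.00857, and adjusted p = 0.791 with an estimated correlation). It also ended when the list was tested with fry (adjusted p = 0.241). Per cell 75 of them were lower, with a median of -0.95.

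Germ cell transcripts were higher in female than in male soma libraries. Meiotic prophase genes rose in 18 of 30 cases (21 higher and 0 lower adjusted over the list alone), germ cell and pluripotency genes in 13 of 24 (14 higher and 0 lower adjusted over the list alone) and piRNA pathway genes in 8 of 18 (11 higher and 0 lower adjusted over the list alone). Meiotic prophase genes had a median log2 fold change of 1.31 (camera adjusted p = 3.71e-08, and adjusted p = 0.463 with an estimated correlation). Germ cell and pluripotency genes had a median log2 fold change of 1.14 (camera adjusted p = 3.13e-05, and adjusted p = 0.463 with an estimated correlation). The piRNA pathway had a median log2 fold change of 0.96 (camera adjusted p = 0.000503, and adjusted p = 0.545 with an estimated correlation). Smc1b rose by 3.25 ± 0.60, Dazl by 2.21 ± 0.49, Mov10l1 by 2.21 ± 0.52 and the germ cell gene Taf7l by 3.37 ± 0.60. The median germ cell and pluripotency gene stood at 4.22%, 3.48% and 0.457% of its female PGC level in female soma replicates 1, 2 and 3, and the median meiotic gene at 2.82%, 11.1% and 0.702%. Stra8 had 10.1, 40.8 and 0.254 CPM in those 3 libraries. Y-linked genes stood at a median of 5.28% of the male soma level in female soma replicate 2, against 0.116% and 0.336% in replicates 1 and 3. The genes did not move alike in replicate 2, where Ddx3y had 33 reads, Eif2s3y 28, Kdm5d 7, Uba1y 3 and Uty 0. Male soma markers were low in that library, with Cyp17a1, Amh and Star at 1.69, 2.45 and 2.15 CPM. Each male soma library held at least 1340, 385 and 409 CPM of these markers. Without female soma replicates 1 and 2 and female PGC replicate 2, the medians were 0.11 for the pluripotency list (camera adjusted p = 0.296) and 0.07 for the piRNA list (camera adjusted p = 0.222), while the meiotic list passed (0.000241) with its median reduced from 1.31 to 0.46. Female soma was then a single library, without a spread of its own. In that setting the extracellular matrix median was 0.0019 and the erythroid median 0.86. With voom the piRNA call ended at a larger median of 1.89 (camera adjusted p = 0.0513). In all, 13 lists were called between the soma groups and 6 with an estimated correlation: Leydig cell, pregranulosa cell, Sertoli cell, mesonephric epithelium, Y-linked and X-linked escape.

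**Figure D4:**
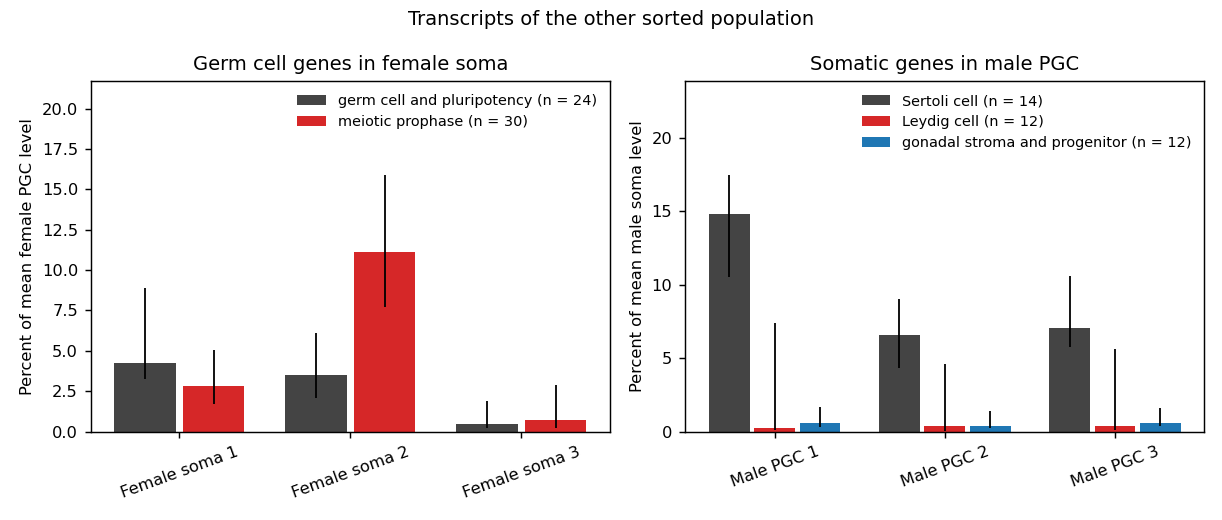
Median level over the members of a gene list, as a percent of the mean level in the other sorted population of the same sex (bars), with lower and upper quartiles over genes (lines), for germ cell lists in the 3 female soma libraries (left) and somatic lists in the 3 male PGC libraries (right). Meiotic genes reach 11.1% in female soma replicate 2, and Sertoli genes lie between 6.6% and 14.8% in male PGCs while Leydig and stroma genes stay under 1%. Not drawn are pregranulosa genes, at 29.1% to 37.5%, and endothelial genes, at 5.37% to 7.42%, in the same male PGC libraries. Male soma is not the tissue of pregranulosa cells, so their percents do not compare with those of Sertoli genes.

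The difference between PGCs and soma itself differed between the sexes for many genes. By read depth the PGC minus soma log2 fold change was higher in females than in males for 3588 genes and lower for 3708, and per cell for 5498 and 663, with a median of 0.91 over all genes. The 6 largest differences were those of Xist (-8.76 ± 0.61), the steroid enzymes Cyp17a1 (7.60 ± 0.48) and Cyp11a1 (6.75 ± 0.50), Pmaip1 (-6.87 ± 0.40), Cbln1 (6.79 ± 0.18) and the secretin gene Sct (6.64 ± 0.20), all with adjusted p of 1.81e-07 or lower. Sct stood at 28.5 ± 2.14 CPM in male soma and 13.8 ± 2.60 in female PGCs, against 0.0729 ± 0.0646 in male PGCs and 0.162 ± 0.167 in female soma. The PGC minus soma log2 fold change of Leydig cell genes was higher in females in 10 of 12 cases (10 higher and 2 lower adjusted over the list alone) and that of Sertoli cell genes in 9 of 14 (9 higher and 1 lower adjusted over the list alone). Leydig cell genes had a median difference between sexes of 4.19 (camera adjusted p = 4.02e-06, and adjusted p = 0.0305 with an estimated correlation). Sertoli cell genes had a median difference between sexes of 1.57 (camera adjusted p = 0.0293, and adjusted p = 0.565 with an estimated correlation). The median PGC minus soma log2 fold change was -4.76 in males and -1.16 in females for Leydig genes, and -2.17 and -0.93 for Sertoli genes, and in females neither list was called by read depth (camera adjusted p = 0.225 and 0.124). Per cell these medians were -7.04 and 0.67 for Leydig genes and -1.89 and -0.03 for Sertoli genes, and in females both lists were called lower relative to all other genes (camera adjusted p = 0.00639 and 0.00359). The Sertoli call ended in the cell number table (median 1.06, camera adjusted p = 0.514) and with voom, where the median was 0.12 (camera adjusted p = 0.598). The PGC minus soma log2 fold change was lower in females for 9 of 9 genes of the male germ cell programme (0 higher and 9 lower adjusted over the list alone), 19 of 24 germ cell and pluripotency genes (0 higher and 19 lower adjusted over the list alone) and 10 of 18 piRNA genes (0 higher and 10 lower adjusted over the list alone). Male germ cell programme genes had a median difference between sexes of -2.32 (camera adjusted p = 7.7e-05, and adjusted p = 0.0594 with an estimated correlation). Germ cell and pluripotency genes had a median difference between sexes of -1.95 (camera adjusted p = 7.7e-05, and adjusted p = 0.565 with an estimated correlation). The piRNA pathway had a median difference between sexes of -1.10 (camera adjusted p = 0.0293, and adjusted p = 0.628 with an estimated correlation). The log2 fold change was also lower in females for 29 of 34 ribosome biogenesis genes (0 higher and 30 lower adjusted over the list alone), 56 of 76 ribosomal protein genes (5 higher and 57 lower adjusted over the list alone), 17 of 32 translation factors (0 higher and 17 lower adjusted over the list alone) and 22 of 39 RNA polymerase II genes (5 higher and 22 lower adjusted over the list alone). Ribosome biogenesis genes had a median difference between sexes of -0.88 (camera adjusted p = 1.25e-10, and adjusted p = 0.389 with an estimated correlation). Cytosolic ribosomal protein genes had a median difference between sexes of -0.38 (camera adjusted p = 4.57e-08, and adjusted p = 0.565 with an estimated correlation). Translation factors had a median difference between sexes of -0.28 (camera adjusted p = 0.00105, and adjusted p = 0.565 with an estimated correlation). RNA polymerase II genes had a median difference between sexes of -0.30 (camera adjusted p = 0.00728, and adjusted p = 0.435 with an estimated correlation). Per cell 4 ribosome biogenesis genes were lower and 1 higher, with a median of -0.25. The per-cell medians of the ribosomal protein, translation factor and RNA polymerase II lists were 0.45, 0.57 and 0.53, below the median of 0.91 over all genes, and these lists were no longer called (camera adjusted p = 0.0521, 0.315 and 0.216). The piRNA call ended without female soma replicate 2 (median -0.79, camera adjusted p = 0.0627), without the 3 female libraries (median -0.37, camera adjusted p = 0.239) and with voom (median -2.175, camera adjusted p = 0.162). Without the 3 female libraries the median difference of germ cell and pluripotency genes was -1.28. The germ cell lists carry the female soma transcripts given above, and 1 of the 9 called lists, Leydig cell, was called with an estimated correlation.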

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

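The tests of the size of the shift, of germ cell transcripts in female soma and of Sertoli transcripts in male PGCs were all chosen after the values per library were seen, while the counts over other splits of the libraries were planned. The results below stood out because the difference between PGCs and soma differed between the sexes.

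The shift per cell was larger in females by 0.99 log2 units. Whether scaling of male soma replicate 3 alone was the whole cause is not settled. The difference without that library was 0.676 ± 0.14, or 68.3% of the full difference. That SE takes the male soma spread only from the remaining libraries, with medians of 4.33 and 4.29, while the SE with all libraries was 0.342. The rule for reading the value was also tightened after it had been seen. More low-RNA erythroid cells in the female soma could lower its median and remain open, with erythroid genes higher per cell in female soma by a median log2 fold change of 0.771. The library medians were 5.83 ± 0.0433 in male and 5.94 ± 0.126 in female PGCs, and 4.62 ± 0.545 in male and 3.74 ± 0.191 in female soma (SD). Most of the difference therefore lay in the soma libraries, which argues against germ cell output as its main source. A difference between the sexes in somatic output remains open and was not tested apart from the scaling and erythroid explanations. A small contribution of germ cell output was not tested either.

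Germ cell transcripts stood out in female soma replicates 1 and 2. In replicate 2, whole germ cells carried over were argued against as the only source. Meiotic genes stood there at 11.1% of their female PGC level and pluripotency genes at 3.48% (permutation p = 8e-05 over genes, which are not independent). Male germ cells as the only source were argued against by 40.8 CPM of Stra8, above each male PGC library. A share of male cells beside female germ cells was not tested. Y-linked genes stood at a median of 5.28% of the male soma level in this library, with Ddx3y at 33 reads, Eif2s3y 28, Kdm5d 7, Uba1y 3 and Uty 0. Germ cells past meiotic entry with little reporter signal may account for the germ cell transcripts of replicate 2 (11.1% for meiotic genes), as a hypothesis. The sort should nevertheless remove germ cells with reporter signal. In replicate 1 whole germ cell carry-over remains open, at 2.82% and 4.22% (permutation p = 0.058).

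Sertoli transcripts in the male PGC libraries stood at a median of 9.75% of the male soma level, against 0.29% for Leydig genes. This gap argued against carry-over of the whole male soma as their only source (permutation p = 0.00037 over genes). Pregranulosa genes stood at 29.1%, 37.5% and 30.8% of the male soma level in replicates 1, 2 and 3. Male soma is not the tissue of these cells, with Foxl2 at 1.09, 0.766 and 1.74 CPM. Those percents therefore do not compare with the percents of Sertoli genes. Endothelial genes stood at 7.42%, 6.21% and 5.37%, and the source of these 2 lists was not tested. Sertoli cells or their RNA sorted with germ cells could account for the Sertoli transcripts and remain open. That 11 of 14 Sertoli genes were highest in male PGC replicate 1 does not decide it, since the replicate was picked after its levels had been seen. Amh was at 67.6, 30.6 and 27.7 CPM in the 3 male PGC libraries.

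By read depth the PGC minus soma log2 fold change was higher in females for 3588 genes and lower for 3708. Among gene lists, the median difference between sexes was -1.95 for germ cell and pluripotency genes, -1.10 for the piRNA pathway, -2.32 for the male germ cell programme, 1.57 for Sertoli and 4.19 for Leydig genes. It was -0.88 for ribosome biogenesis, -0.28 for translation factors, -0.30 for RNA polymerase II genes and -0.38 for ribosomal protein genes. The largest gene differences were Xist (-8.76), Cyp17a1 (7.60), Pmaip1 (-6.87), Cbln1 (6.79), Cyp11a1 (6.75) and Sct (6.64).

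Splits of the libraries were counted, and the real grouping is 1 of the splits in each count. For PGCs against soma as the mean of both sexes, chance was argued against for the number of genes. Only the real split, 1 of 100, gave as many, per cell (11656, the highest other split 9614) and by read depth (11138 and 6638). For lists, 3 of 100 splits gave as many, and the highest other split also gave 22. The number of lists therefore does not set the real grouping apart. For genes differing between the sexes in their PGC to soma difference, 2 of 100 splits gave as many (7296), and the highest other split, 7711, exchanged the sex of all soma libraries. For lists in that comparison chance was not excluded, since 80 of 100 splits gave at least 9 lists and the highest other split 18. The 10 splits of 3 against 3 are too few for a share under 0.05. Per cell the counts were 10756 in males and 11403 in females, and by read depth 10633 and 10407, each with 0 genes in the highest other split (limma, against up to 810, 86, 117 and 390 at an unadjusted p under 0.05). In each, 1 of 10 splits gave as many. Between PGC groups 8381 genes passed against 0 in the highest other split (limma, up to 524 unadjusted), and 1 of 10 splits gave as many. Between soma groups 3130 passed against 6 (limma, up to 834 unadjusted). The 13 lists of the PGC and soma sex comparisons had highest other splits of 16 and 16, with 7 and 5 of 10 splits giving as many.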

How the results depend on the processing

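Leaving out 3 female libraries, voom on reads and reads per effective size were chosen after the data were seen. The shift of 1.70 log2 units kept its direction in each alternative on the cell number table, but the read depth table gave -0.22 for the mean, -0.25 in males and -0.20 in females. Leaving out each library gave 1.62 to 1.86, in males 1.04 to 1.52, in females 2.12 to 2.31, and for the difference between sexes 0.68 to 1.16. The male shift was 1.68 over genes above the median level and 1.63 by reads per effective size. The female shift was 1.88 from library means, 2.57 over genes above the median level, 2.42 without the lowest 25% of genes and 2.43 by reads per effective size. The difference between sexes no longer passed over genes above the median level (0.89, exact p = 0.055), by reads per effective size (0.80, exact p = 0.095) and without 3 female libraries (0.83, exact p = 0.275). Without the lowest 25% of genes, genes lower in PGCs numbered 800 per cell, 1114 in males and 508 in females, and by read depth 3817, 3641 and 3586, with fewer genes tested. In that setting 879 genes were higher in female soma. Median centring gave 6446 higher and 4855 lower by read depth, 6200 higher and 5054 lower per cell, 4785 lower in males, and 5690 and 4675 in females. Quantile normalization gave 6162 and 4883, 4574 lower in males, and 5760 and 4583 in females. The other table gave 5321 and 5817 for the per-cell mean, 5026 and 5607 in males, and 4968 and 5439 in females. In the reverse direction it gave 9541 and 2115, 8215 and 2541, and 9922 and 1481, with 2279 lower in female PGCs, 367 and 8171 in soma, and 5498 and 663 for the difference between sexes. A log2 change of at least 1 left 1545 and 3034 by read depth, 1905 and 3242 in males, 1669 and 3001 in females, 1315 and 876 between PGCs, 421 and 347 between soma, and 1457 and 1167 for the difference between sexes. Per cell, Cdkn1b turned to 0.0632, Mki67 to 1.55, Dnmt3a to 0.27, Fn1 to 1.40, Gapdh to 1.48, Actb to 0.66 and Atp5a1 to 1.88 in PGCs against soma, and Kdm6a to -0.16 between soma groups. Without 3 female libraries 725 and 714 genes differed between soma groups, with 1 female soma library left and its spread taken from the other groups. That setting ended the immediate early call in PGCs against soma (camera adjusted p = 0.069), the pluripotency (0.296) and piRNA (0.222) calls between soma, and the piRNA call for the difference between sexes (0.239), at medians of -1.22, 0.11, 0.07 and -0.37. Between soma the meiotic median went from 1.31 to 0.46, the erythroid from 1.36 to 0.86, the oxidative phosphorylation from -0.06 to -0.10 and the extracellular matrix from -0.15 to 0.0019, and the difference between sexes of germ cell and pluripotency genes from -1.95 to -1.28. With an estimated correlation 0 of 22, 0 of 13, 6 of 13 and 1 of 9 lists were called, in the order PGCs against soma, PGC sexes, soma sexes and their difference, for which fry gave 19 and omitting female PGC replicate 3 gave 14. No pairing of samples by replicate number was seen (correlations -0.282 to 0.0334 per cell, -0.361 to 0.0715 by read depth), which cannot show that the samples were unpaired. A replicate block left 9506 higher and 2095 lower per cell and 13 lists for the difference between sexes. The cell number table ended 7 list calls (camera adjusted p): male germ cell programme (0.382) and immediate early (0.0514) in PGCs against soma, chromatin (0.0854) between PGCs, and Sertoli (0.514), translation factor (0.315), RNA polymerase II (0.216) and ribosomal protein (0.0521) for the difference between sexes. Voom gave 9575 and 2071 per cell and 4525 and 6539 by read depth, and ended 10 list calls: male germ cell programme (0.121), Sertoli (0.0759), pregranulosa (0.121), endothelial (0.0759), erythroid (0.0587) and immediate early (0.138) in PGCs against soma, Sertoli between PGCs (0.087), piRNA between soma (0.0513), and Sertoli (0.598) and piRNA (0.162) for the difference between sexes. Their voom medians were larger in size except that of Sertoli for the difference between sexes, at 0.12. Fry ended the oxidative phosphorylation call between soma (adjusted p = 0.241). The array weights fit stopped short of its convergence tolerance. The cause of these changes was not tested. Depth left only a lower bound on the fold change where a group had 0 reads, such as 401-fold for Ddx3y. Every gene reached 5.07 CPM in at least 3 libraries, so genes below that filter were not analysed here.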

Other observations

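The test of X-linked genes was planned before its values were seen, and the comparison of single genes was added afterwards. X-linked genes were higher in female than in male PGCs. Over 480 X-linked genes without Xist and 12288 autosomal genes, the library median of X-linked relative to autosomal genes was -0.904, -1.05 and -0.901 log2 units in male PGCs and 0.112, 0.129 and -0.0308 in female PGCs. The difference between the sexes was 1.02 ± 0.071 (SE, 2.03-fold, exact permutation p = 0.1, the smallest possible) in PGCs and -0.04 ± 0.058 in soma (exact p = 0.6). In soma the male values were -0.368, -0.33 and -0.319 and the female values -0.411, -0.274 and -0.462. Gene by gene, 262 X-linked genes (54.6%) were higher and 68 (14.2%) lower in female PGCs by read depth, against 32% and 33.2% of autosomal genes, and 19.2% and 12.5% of X-linked genes in soma. The median of single-gene log2 fold changes on reads was smaller than the difference of medians, at 0.719 for X-linked and 0.0581 for autosomal genes in PGCs.

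The hypothesis that both X chromosomes were transcribed in female PGCs but not in female soma predicted a larger difference in PGCs. The difference between the comparisons was 1.07 ± 0.091 (exact permutation p = 0.03), in the predicted direction. Allele-resolved reads were not used here, so this remains a hypothesis, and no other explanation was tested. Xist stood at 3.13, 15.0 and 1.43 CPM in the female PGC libraries and at 1920 to 2160 CPM in female soma. A lower X-linked output in male PGCs could contribute and remains open, since their values lay below those of male soma (1.07 holds both). It would not by itself place female PGCs above female soma, unless PGCs and soma also differ in X-linked output for another reason.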
